A study of Mus musculus with 10 samples.

How the data were processed

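RNA sequencing was done on 10 oocyte libraries, 3 young, 3 aged and 4 spermidine, grouped by their titles. The submitters' processing notes name Bowtie2 2.3.4.3, RSEM 1.3.1, DESeq2 1.4.5 and the genome build mm9, with no role or order. The authors deposited 1 table of 18493 genes with an expected count per gene and library, per the file headers a read count, of which 15.9% to 16.7% were not whole numbers in a library. The same deposited table holds the authors' log2 fold changes and their p-values and q-values for spermidine against aged and aged against young. Strand use in counting was not given in the sources used here, so overlapping and antisense genes cannot be told apart. The 13 mitochondrially encoded genes of a fixed list were not analysed here.

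Expected counts were rounded to whole numbers. With R 4.3.3 and edgeR 4.0.16, genes were kept by filterByExpr, libraries scaled by TMM, and 12315 genes tested by the quasi-likelihood F test with robust dispersion, in 1 fit over all 10 libraries with a mean per group. Adjusted p-values are Benjamini-Hochberg over genes in each of 3 comparisons, with a threshold of 0.05. Log2 fold changes carry the SE implied by the F statistic. CPM values, counts relative to the TMM-scaled library total, were computed from the counts. Totals were 24222185 to 28730790 counts, which sets the precision of low genes; floors of 3 counts and intervals cover counting error only, since reads carried no molecular identifiers.

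Of 26 gene lists fixed before the data were examined, 25 were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 genes) and adjusted over the lists. An estimated correlation and fry were alternatives, and list medians were set against 10000 random lists matched in 5 expression and 10 length classes. The random lists were drawn gene by gene, so their spread leaves out correlation between the genes of a list. The lists were mitophagy, autophagosome formation, lysosome, nuclear and mitochondrially encoded oxidative phosphorylation, mitochondrial dynamics, mitochondrial ribosome, tricarboxylic acid cycle, fatty acid oxidation, glycolysis, polyamine metabolism, antioxidant defence, DNA damage response, apoptosis, oocyte-specific genes, sperm binding, spindle, cohesin, maternal mRNA storage, DNA methylation, proteasome, endoplasmic reticulum chaperones, cytosolic ribosomal proteins, and markers of granulosa, theca and blood cells.

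Genes named in the text followed a rule, in its order. It takes up to 10 higher and 10 lower genes per comparison by fold change, among those that passed, with at least 20 CPM in the higher group and no overlap between groups, leaving out predicted genes. It adds up to 4 genes of smallest p per list and up to 10 genes that passed in both comparisons in opposite directions. Changes in opposite directions, and changes shared by the comparisons with young, were set against libraries simulated without group effects. The alternatives were RLE factors, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, only the 2 groups compared, a replicate block, no robust fit, a fold threshold and each library left out. Per-transcript values were not analysed here. Length and GC correction, total count scaling, leaving out aged replicate 1 with spermidine replicate 1, and classes of libraries by GC trend were added after seeing the data. Transcript length and GC content came from a GRCm38 annotation by Gene ID for 97.7% of tested genes; it is not the mm9 build, so no coordinates are given.

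The procedure was tested on simulated data with 12136 genes in the fit. For aged minus young it recovered 48% of genes changed by 1 on the log2 scale and 94% of those changed by 2, with 7 false calls among 150. For spermidine minus aged it recovered 60% and 99% with 8 false calls among 167, and for spermidine minus young 61% and 99.5% with 19 among 342. The simulated genes varied independently, with no trend shared across a library, so these rates need not hold for the real libraries. The changes by 1 and 2 were placed only in genes with a mean of at least 1 CPM, so the recovery rates do not cover lower genes. A smaller shift was also placed on the oxidative phosphorylation list, and calls of its genes were not counted as false in the comparisons with young. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.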

Results

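The data were RNA sequencing profiles of mouse oocytes from the ovary, made by the SMART-seq2 method, in which polyadenylated RNA is reverse transcribed from an oligo dT primer into full-length cDNA and then amplified. The levels given here are therefore those of RNA captured by its poly(A) tail, and tail length was not measured. Oocytes fell into 3 groups, young (n = 3 libraries), aged (n = 3) and spermidine (n = 4), the last described in the labels as a rescue. The labels give no age for that group's animals beyond this, and its libraries were taken as aged oocytes with spermidine. Spermidine is a polyamine, a small positively charged metabolite. By its title and design text the series asks how transcript levels of oocytes differ between young and aged females and with spermidine, with mitophagy, the autophagic removal of mitochondria, as its theme.

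Library totals lay between 24222185 and 28730790 counts, and 15326 to 15711 genes had at least 1 count. The 10 most abundant genes took 18.5% to 23.1% of the counts of a library. Clec16a, with 6.21% of counts on average, and Gdf9, an oocyte growth factor gene, were among them. Clec16a, Hexdc, Hddc3 and Dnajc14 ranked 1 to 4, and each was lowest in spermidine replicate 1 and next lowest in aged replicate 1. Whether their values stand for separate transcripts was not tested. These genes are named for their abundance, after their values were seen. Of 18493 genes in the table, 12315 were tested. The libraries also differed in other ways than their group. The correlation, across genes, of a library's expression deviations with transcript length was 0.450 in aged replicate 1 and 0.194 in spermidine replicate 1, against -0.240 to -0.108 in the young libraries, and genes are not independent replicates. The correlation with GC content ran from -0.331 in young replicate 3 to 0.405 in aged replicate 3. Haemoglobin transcripts summed to 19.9 CPM in young replicate 1, 13.5 CPM in young replicate 3 and 9.61 CPM in aged replicate 1, and to at most 0.109 CPM in the other 7 libraries. The labels say nothing of separate animals or pools behind the libraries, so p-values measure the spread between these samples, which may be technical.

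**Figure D1:**
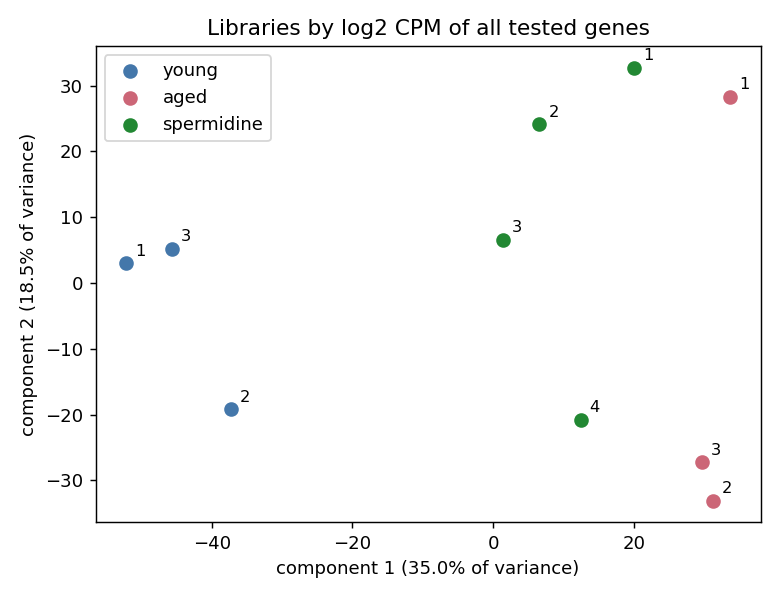
Principal components of the log2 CPM of all 12315 tested genes, one point per library, numbered by replicate; the axes are component scores with no unit. On the first component (35.0% of variance) the 3 young libraries lie at negative scores and all others at positive scores, and on the second (18.5%) aged replicate 1 lies with spermidine replicates 1 and 2, away from aged replicates 2 and 3 and spermidine replicate 4.

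Between aged and young oocytes, 1196 of 12315 tested genes were higher and 993 lower in aged oocytes, and 940 of these 2189 changed by at least 2-fold. Manba (Gene ID 110173), which encodes the lysosomal enzyme beta-mannosidase, rose from 0.339 CPM ± 0.101 (SD, n = 3) to 64.5 CPM ± 7.47 (SD, n = 3). Agtpbp1 (Gene ID 67269), which encodes a tubulin deglutamylase, fell from 166 CPM ± 8.95 (SD, n = 3) to 25.0 CPM ± 2.43 (SD, n = 3). Of 87 tested nuclear genes of oxidative phosphorylation, 30 fell and 0 rose, and camera placed this list below the other genes with its preset correlation but not with an estimated one (adjusted p = 0.918 with an estimated correlation).

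Other large increases, in each of which the groups did not overlap, were those of Dbt, a subunit of the branched-chain keto acid dehydrogenase (log2 fold change 4.75, SE 0.41), and Srgn, the proteoglycan serglycin (4.01, SE 0.57). The value of Srgn ran from 3.57 to 5.08 with 1 library left out, and its young libraries stood at 8.85, 2.12 and 1.73 CPM. Next came the germ cell gene Tex15 (3.21, SE 0.54) and the circadian gene Per3 (2.15, SE 0.22). Those of Cnep1r1 (2.12, SE 0.20), Tceal8 (2.11, SE 0.15), Rilpl1 (2.11, SE 0.21) and Ccdc105 (1.96, SE 0.18) followed. Il20ra, an interleukin receptor gene, had 0 counts in the young group and 1754 in the aged group. Against a floor of 3 counts over the young group it was at least 509-fold higher in aged oocytes, and its call (edgeR adjusted p = 0.0177) was lost without young replicate 1, young replicate 3 or any 1 of the aged libraries. The largest decreases beside Agtpbp1 were those of Sirpb1c (-3.57, SE 0.32), Cd200 (-3.19, SE 0.34), which encodes a cell surface glycoprotein, the mitochondrial branched-chain aminotransferase gene Bcat2 (-2.90, SE 0.57) and Slc23a3 (-2.77, SE 0.32). They were followed by Btla (-2.03, SE 0.24), Slc12a8 (-1.99, SE 0.41), the meiotic chromosome axis gene Hormad1 (-1.97, SE 0.25), Gtf2a1l (-1.84, SE 0.21) and Utp23 (-1.82, SE 0.24). The call of Bcat2 (adjusted p = 0.0066 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) was lost without aged replicate 1. Those of Bcat2, Slc12a8 and Il20ra were lost without aged replicate 1 and spermidine replicate 1 together, and that of Il20ra also without a filter. Libraries were also classed, after the data were seen, as high or low by the sign of their GC trend, which leaves young replicate 2 the only young library of the high class. The call of Il20ra was lost with this class as a term, and those of Cd200 and Slc12a8 in the high class.

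Among the nuclear genes of oxidative phosphorylation, a list that also takes in assembly factors by their names, the genes of smallest p encode subunits of respiratory complex I, Ndufa8 (-0.84, SE 0.14), Ndufa6 (-0.87, SE 0.16) and Ndufb10 (-0.81, SE 0.16). The list had 41 genes lower and 0 higher when adjusted over the list alone and a median log2 fold change of -0.40 (camera adjusted p = 1.87e-11, from 4.78e-15 to 0.918 over its alternatives). Of 78 mitochondrial ribosome genes, 28 fell and 1 rose (42 lower and 1 higher adjusted over the list alone). Mrpl20 (-1.17, SE 0.17) and Mrpl46 (-0.79, SE 0.14) fell, and the 1 that rose was Mrpl17 (0.57, SE 0.15), named after its value was seen. Of 75 cytosolic ribosomal protein genes, 16 fell and 0 rose (24 lower and 1 higher adjusted over the list alone), with Rps18 (-0.73, SE 0.15) and Rpl23 (-0.95, SE 0.22). Of 31 proteasome genes, 9 fell and 0 rose (15 lower and 0 higher adjusted over the list alone), with Psma7 (-0.58, SE 0.12) and Psma3 (-0.62, SE 0.15). Camera called each of these 3 lists lower, with medians of -0.42, -0.36 and -0.32 (camera adjusted p = 1.63e-09, 1.68e-08 and 8.06e-05), and none of them with an estimated correlation (adjusted p = 0.918 with an estimated correlation). Over the alternatives camera's adjusted p began at 4.26e-11, 4.78e-15 and 9.26e-08 and ended at that 0.918. Among 10000 random lists matched in expression and length, the medians of the oxidative phosphorylation, mitochondrial ribosome, cytosolic ribosomal and proteasome lists lay at percentiles 0.03, 0, 2.86 and 4.01, where the random lists centred on -0.26, -0.15, -0.29 and -0.21. The cytosolic ribosomal and proteasome medians were the less extreme, and these percentiles take no account of genes that move together. Transcript length and GC trends differed between libraries as given above, and the median transcript was 1200 bases long in the oxidative phosphorylation list and 1106 bases in the cytosolic ribosomal list. After correction for length and GC content their medians were -0.23 and -0.18, with 17 of 85 and 6 of 75 genes lower, as were 24 mitochondrial ribosome and 6 proteasome genes, and with total count scaling the medians of the oxidative phosphorylation, cytosolic ribosomal and proteasome lists were -0.25, -0.21 and -0.18. The cytosolic ribosomal call was lost with fry and in the high GC class (median -0.11, adjusted p = 0.122).

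Mitophagy genes moved both ways. Nipsnap1 (-1.24, SE 0.16) and Tomm7 (-0.62, SE 0.17), which encode mitochondrial proteins, fell, and the autophagy genes Ambra1 (0.96, SE 0.21) and Optn (0.80, SE 0.20) rose. With Mfn2 (0.68, SE 0.20) higher and Bnip3 (-0.53, SE 0.14) lower, 3 of 27 rose and 3 fell, also when adjusted over the list alone, and the list did not pass (median 0.23, camera adjusted p = 0.894). After length and GC correction 2 rose and 1 fell. Of 34 autophagosome genes 5 rose and 2 fell (5 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.606). The membrane fusion gene Stx17 (1.04, SE 0.18), Epg5 (1.23, SE 0.25), Atg9a (1.09, SE 0.24), Pik3r4 (0.80, SE 0.18) and Atg7 (0.76, SE 0.23) were higher, and Vamp8 (-1.02, SE 0.17) and Atg10 (-0.91, SE 0.23) lower. Of 39 lysosome genes 7 rose and 0 fell (9 and 0 adjusted over the list alone), among them Glb1 (1.45, SE 0.20) and the cholesterol transporter gene Npc1 (1.59, SE 0.27), and the list did not pass (camera adjusted p = 0.135), but did under a stricter filter, with fry, in the high GC class, without aged replicate 1 and spermidine replicate 1 together, and without aged replicate 1 alone (adjusted p = 0.0342, from 0.00560 over its alternatives to an adjusted p = 0.918 with an estimated correlation). Bnip3, Pik3r4, Atg7, Atg10 and, in this list, Mfn2 were named after their values were seen.

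Other mitochondrial and metabolic lists did not pass either. Of 18 genes of mitochondrial dynamics the fission gene Fis1 (-0.58, SE 0.14) fell and Mfn2 and Mief1 (0.77, SE 0.24) rose (camera adjusted p = 0.756). Of 20 genes of the tricarboxylic acid cycle and pyruvate entry 3 rose and 6 fell (camera adjusted p = 0.367). Pdha1 (0.90, SE 0.15) of pyruvate dehydrogenase, Dlst (0.77, SE 0.22) and Cs (0.59, SE 0.17) were higher and the pyruvate carrier gene Mpc2 (-0.59, SE 0.14) lower. Acadm (-0.68, SE 0.14) and Hadhb (-0.51, SE 0.15) fell among 13 genes of fatty acid oxidation, and Ldha (-1.81, SE 0.54) fell and Pfkm (0.87, SE 0.27) rose among 15 of glycolysis (camera adjusted p = 0.519 and 0.825). Adjusted over the list alone, these 4 lists had 2 higher and 1 lower, 3 and 6, 0 and 2, and 0 and 0. Keap1 (0.98, SE 0.29) was the 1 gene of 23 of antioxidant defence that passed, with 0 adjusted over the list alone (camera adjusted p = 0.894). Among 18 polyamine metabolism genes 0 passed by edgeR, 4 had an unadjusted p under 0.05 and 1 passed by DESeq2, and 0 passed adjusted over the list alone (camera adjusted p = 0.961). The first by p was Smox (0.56, SE 0.19), which encodes spermine oxidase.

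Of 29 oocyte-specific and maternal-effect genes 5 rose and 2 fell (6 and 3 adjusted over the list alone). The germ cell helicase gene Ddx4 (1.57, SE 0.25), the receptor gene Gpr3 (1.14, SE 0.24), Sohlh2 (1.23, SE 0.31), Nlrp5 (1.03, SE 0.29) and Nlrp2 (0.81, SE 0.24) were higher. Oosp2 (-0.91, SE 0.17) and Figla (-0.56, SE 0.15) were lower. Nlrp5, Nlrp2 and Figla were named after their values were seen. Of 28 genes of maternal mRNA storage and decay 6 rose and 0 fell (7 and 0 adjusted over the list alone), with Cpeb1 (0.89, SE 0.20), a regulator of mRNA polyadenylation, and Pan2 (0.74, SE 0.18). Of 40 spindle genes 4 rose and 0 fell, the kinetochore gene Ndc80 (1.13, SE 0.14), the separase gene Espl1 (0.90, SE 0.15), Cdc25b (0.90, SE 0.19) and Bub1b (0.72, SE 0.18). The cohesin subunit gene Smc3 (-0.64, SE 0.14) fell and Mau2 (0.73, SE 0.20) rose among 20 cohesin and synaptonemal genes. Fetub (-1.13, SE 0.16) fell and Nsf (1.05, SE 0.18) rose among 14 genes of sperm binding and cortical granules. Of 26 DNA damage genes Parp1 (0.83, SE 0.18), Lig4 (0.92, SE 0.24) and Brca2 (0.83, SE 0.24) rose. Among 13 apoptosis genes Cycs (-0.76, SE 0.18) fell and Bcl2l1 (1.26, SE 0.36) and Casp9 (1.04, SE 0.32) rose. Among 23 DNA methylation and histone modifier genes Kdm5b (1.16, SE 0.22), Uhrf1 (0.70, SE 0.17) and Dnmt1 (0.62, SE 0.15) rose and Tet1 (-0.66, SE 0.21) fell. Among 21 genes of endoplasmic reticulum chaperones the stress sensor gene Ern1 (1.31, SE 0.24), Edem1 (1.48, SE 0.27), Trib3 (2.42, SE 0.76) and Eif2ak3 (0.87, SE 0.27) rose. Dnajb9, from 7.20 CPM ± 0.317 (SD, n = 3) to 3.59 CPM ± 0.205 (SD, n = 3), and Dnajc3 (-0.43, SE 0.12) fell. Trib3 and Eif2ak3 were named after their values were seen. Adjusted over the list alone the lists from spindle to chaperones had, in this order, 4 higher and 0 lower, 1 and 1, 1 and 1, 3 and 0, 3 and 2, 4 and 2, and 4 and 3. None of the lists from oocyte-specific genes to chaperones passed camera in the fit described above, and the smallest camera adjusted p was 0.171, for maternal mRNA. After length and GC correction, chosen after the data were seen, the oocyte-specific list passed as higher, with 6 genes higher and 0 lower and a median of 0.46 against 0.33 before (camera adjusted p = 0.00167, from 0.000152 to 0.936 over its alternatives, and adjusted p = 0.855 with an estimated correlation). It also passed in the high GC class and without aged replicate 1 and spermidine replicate 1 together, and the maternal mRNA list passed as higher without a filter, under a stricter one, in the low GC class and with the class as a term (adjusted p from 0.0118 over its alternatives to an adjusted p = 0.918 with an estimated correlation). With fry, which asks whether a list's genes move one way and compares them with no other genes, the DNA damage and spindle lists passed as higher (adjusted p = 0.0454 for both, from 0.0454 over their alternatives to an adjusted p = 0.918 with an estimated correlation). In the low class, where aged replicate 1 is the only aged library, the DNA methylation list also passed as higher and the tricarboxylic acid cycle list as lower (adjusted p = 0.0379 and 0.0288, each the lowest over its alternatives, up to an adjusted p = 0.936 with an estimated correlation).

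Markers of other cells were few. The granulosa cell receptor gene Fshr (1.79, SE 0.41) and Nr5a2 (0.61, SE 0.20) rose among 6 tested granulosa and cumulus markers (3 higher and 1 lower adjusted over the list alone). By edgeR 0 of 5 theca and stromal and 0 of 9 blood and immune markers passed, with 1 and 2 at an unadjusted p under 0.05 and 0 and 1 by DESeq2. These 3 lists did not pass (camera adjusted p = 0.894, 0.502 and 0.519), and haemoglobin summed to at least 9.61 CPM in young replicates 1 and 3 and aged replicate 1 alone. The median and mean of the antioxidant and apoptosis lists were above 0 while camera's direction was down, and the granulosa list had a median above and a mean below 0.

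The 2189 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg threshold of 0.05, and 4922 genes had groups that did not overlap, where chance gives 10% of genes. The count was 827 without young replicate 1, 1031 without young replicate 3, 1359 without aged replicate 2, 1426 without aged replicate 3 and 1179 under a stricter filter on low counts. Of 72 list members named by rule that passed, 30 kept their call whichever library was left out, 40 losing it without young replicate 1 and 35 without young replicate 3. Scaling by total counts moved the median log2 fold change of all genes from 0.10 to 0.24 and the split to 1236 higher and 405 lower. The split was 1090 higher and 1110 lower with RLE factors and 1434 and 1453 with DESeq2. It was 959 and 1003 with only the 2 groups in the fit, and 894 and 976 after length and GC correction. Which direction held more genes therefore depended on the processing.

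Between spermidine and aged oocytes, 298 of 12315 genes were higher and 300 lower with spermidine, and 225 of these 598 changed by at least 2-fold. Anxa5 (Gene ID 11747), which encodes the phospholipid-binding protein annexin A5, rose from 34.9 CPM ± 2.33 (SD, n = 3) in aged oocytes to 115 CPM ± 26.5 (SD, n = 4). H2-T22, a histocompatibility gene with close paralogs between which reads can be shared, fell from 35.6 CPM ± 8.79 (SD, n = 3) to 3.59 CPM ± 2.50 (SD, n = 4). Lzts1 (Gene ID 211134) fell from 71.4 CPM ± 22.6 (SD, n = 3) to 12.2 CPM ± 3.51 (SD, n = 4).

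Other genes higher with spermidine were the chemokine gene Ccl2 (log2 fold change 3.70, SE 0.68), Prex2 (1.79, SE 0.33), Galnt6 (1.53, SE 0.34) and the glycerol phosphate acyltransferase gene Gpat3 (1.32, SE 0.18). Next came Vamp8 (1.29, SE 0.17), which encodes a vesicle fusion protein, the lipid phosphatase gene Plpp1 (1.15, SE 0.13), and Cldn34b2 (1.09, SE 0.18). They were followed by Cmtm8 (1.06, SE 0.18) and Tceal8 (1.05, SE 0.13). Lower were Dbt (-1.88, SE 0.32), the zinc finger gene Zfp961 (-1.75, SE 0.20), Rilpl1 (-1.70, SE 0.19), Zfp979 (-1.55, SE 0.19) and Ern1 (-1.50, SE 0.22), which encodes an endoplasmic reticulum stress sensor. Also lower were the oocyte homeobox gene Sebox (-1.37, SE 0.17), Zbed3 (-1.26, SE 0.25) and the microtubule affinity regulating kinase gene Mark2 (-1.23, SE 0.15). The calls of Prex2 and Cmtm8 were lost without aged replicate 2, those of Ccl2 and Galnt6 without any 1 of the aged libraries, that of Zbed3 without aged replicate 2 or 3, and those of Galnt6 and Zbed3 also without spermidine replicate 2 or 3. Those of Ccl2 and Galnt6 were lost without a filter and without aged replicate 1 and spermidine replicate 1 together, those of Galnt6 and Zbed3 with only the aged and spermidine libraries in the fit, and that of Ccl2 with the GC class as a term. The calls of Ccl2, Vamp8, Zfp979 and Ern1 were lost in the high GC class, with 1 spermidine library, and that of Cldn34b2 in the low class, with 1 aged library.

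The nuclear genes of oxidative phosphorylation had 4 of 87 higher and 0 lower over all genes and 30 higher adjusted over the list alone, and the 4 were Ndufb2 (0.89, SE 0.17), Ndufb10 (0.73, SE 0.16), Atp5k (0.81, SE 0.18) and Ndufa6 (0.58, SE 0.15). The median log2 fold change was 0.32 (camera adjusted p = 1.94e-09, from 2.20e-11 to 0.550 over its alternatives, and adjusted p = 0.550 with an estimated correlation). Mrpl39 (0.69, SE 0.14), Mrps15 (0.65, SE 0.14) and Mrpl58 (0.51, SE 0.13) of the mitochondrial ribosome rose, 3 of 78, with 24 higher and 1 lower adjusted over the list alone. This list also passed (median 0.26, camera adjusted p = 6.48e-08, from 2.34e-10 over its alternatives to an adjusted p = 0.550 with an estimated correlation). Among 75 cytosolic ribosomal proteins Rps18 (0.61, SE 0.14) rose, with 0 adjusted over the list alone (median 0.23, camera adjusted p = 2.32e-05, from 2.18e-06 over its alternatives to an adjusted p = 0.790 with an estimated correlation). Aged replicate 1 had the strongest length trend, and after correction for length and GC content these medians were 0.14, 0.17 and 0.08, with 5 mitochondrial ribosome genes higher and 1 lower, and the cytosolic ribosomal list no longer passed (adjusted p = 0.393). In the high GC class, where spermidine replicate 4 is the only spermidine library, neither the mitochondrial ribosome list (median 0.11, adjusted p = 0.149) nor the cytosolic ribosomal list (0.10, adjusted p = 0.126) passed, the latter also not with fry. Among matched random lists the 3 medians lay at percentiles 100, 99.99 and 92.84, where the random lists centred on 0.16, 0.08 and 0.17, so that the cytosolic ribosomal median lay within their spread.

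Camera placed 4 lists below the other genes with its preset correlation. In maternal mRNA storage and decay Cpeb1 (-0.83, SE 0.19) and Cnot3 (-0.72, SE 0.18), a subunit of the CCR4-NOT deadenylase, fell among 28 genes. In the oocyte-specific list Ddx4 (-1.13, SE 0.23), Dazl (-0.70, SE 0.15), an RNA-binding germ cell factor, and Gpr3 (-0.96, SE 0.22) fell among 29. The kinase gene Ttk (-0.55, SE 0.14) fell among 40 spindle genes, and 0 of 26 DNA damage genes passed by edgeR, with 6 at an unadjusted p under 0.05 and 2 by DESeq2. The medians were -0.41, -0.41, -0.21 and -0.28, and the camera adjusted p values 0.00232, 0.0156, 0.0262 and 0.0262, with an adjusted p = 0.550, 0.790, 0.499 and 0.499 with an estimated correlation. Over the alternatives camera's adjusted p ran from 3.06e-05 to 0.550, 1.76e-05 to 0.844, 0.00588 to 0.499 and 0.00714 to 0.499. Adjusted over the list alone, 0 were higher and 2 lower, 1 and 3, 1 and 6, and 0 and 0. The calls of the maternal mRNA and DNA damage lists were lost without aged replicate 1, and those of the oocyte-specific and spindle lists without aged replicate 2, without spermidine replicate 1 and in either GC class, of which the low has 1 aged and the high 1 spermidine library. That of the spindle list was also lost under a stricter filter, that of the oocyte-specific list with the GC class as a term (in the high class its median was -0.07, adjusted p = 0.844), that of the DNA damage list in the high class and without aged replicate 1 and spermidine replicate 1 together, and those of the maternal mRNA and oocyte-specific lists with fry. Among matched random lists the 4 medians lay at percentiles 0, 0, 1.06 and 1.68, where the random lists centred on -0.09, 0.06, -0.06 and -0.09.

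**Figure D2:**
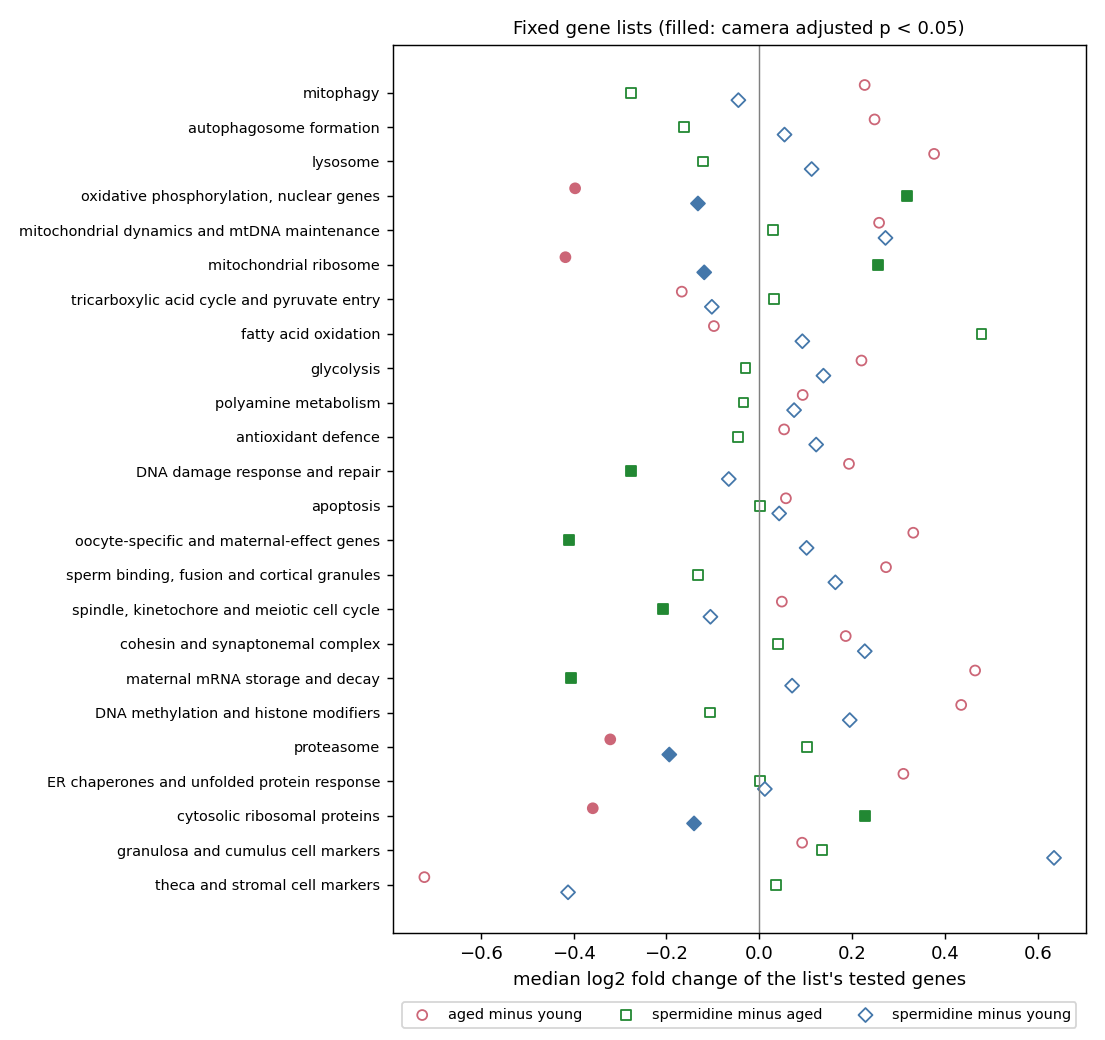
Median log2 fold change (horizontal axis) of the tested genes of each fixed list, one line per list, in the 3 comparisons; filled symbols passed camera with its preset correlation, and none passed with an estimated one. Oxidative phosphorylation lies at -0.40 for aged minus young and 0.32 for spermidine minus aged; the blood and immune list, which held genes at 0 counts, is not drawn.

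Of 27 mitophagy genes, Ambra1 (-0.77, SE 0.19) fell and Nipsnap1 (0.60, SE 0.15) rose, also when adjusted over the list alone, and the list did not pass (median -0.28, camera adjusted p = 0.271). It passed as lower with fry (adjusted p = 0.0453, from 0.0453 to 0.734 over its alternatives, and adjusted p = 0.556 with an estimated correlation). Of 34 autophagosome genes, Vamp8 rose and Atg9a (-0.88, SE 0.21) and Atg14 (-0.52, SE 0.13) fell, the same counts adjusted over the list alone. Of 39 lysosome genes 0 rose and 4 fell (6 adjusted over the list alone), Psap (-1.08, SE 0.24), Arsb (-1.12, SE 0.27), Tfe3 (-0.62, SE 0.15) and Atp6v0c (-0.94, SE 0.24), which encode lysosomal proteins and, for Tfe3, a transcription factor. In other lists Fis1 (0.49, SE 0.13), Mpc2 (0.50, SE 0.13), Rab27a (0.77, SE 0.14) and the stress response factor gene Nfe2l2 (0.82, SE 0.21) rose and Hadha (-0.62, SE 0.15), Dnmt1 (-0.54, SE 0.14) and Ern1 fell, each the 1 gene of its list to pass. Adjusted over the list alone, mitochondrial dynamics had 1 higher and 0 lower, the tricarboxylic acid cycle 2 and 1, sperm binding 1 and 0, antioxidant defence 2 and 0, fatty acid oxidation 5 and 1, DNA methylation 0 and 1 and chaperones 0 and 1. Of the glycolysis, apoptosis and cohesin lists 0 genes passed by edgeR, with 3, 2 and 1 at an unadjusted p under 0.05 and 0, 1 and 0 by DESeq2. Of 18 polyamine metabolism genes 0 passed by edgeR and 0 by DESeq2, with 2 at an unadjusted p under 0.05, and of 31 proteasome genes 0 passed by edgeR and 2 by DESeq2, with 4 at an unadjusted p under 0.05. Of 6 granulosa, 5 theca and 9 blood markers 0 passed by edgeR, with 2, 0 and 3 at an unadjusted p under 0.05 and 1, 0 and 0 by DESeq2. Cd74, a blood and immune marker, had 0 counts in the spermidine group and 29 in the aged group, at 0.934, 0 and 0.037 CPM in aged replicates 1, 2 and 3. The fatty acid oxidation, proteasome and blood lists did not pass (camera adjusted p = 0.0880, 0.125 and 0.166), but all 3 did without aged replicate 2, without aged replicate 3, in the low GC class and with the class as a term, higher for the first 2 and lower for the blood list. Over the alternatives their adjusted p ran from 0.00621 to 0.790, 0.000454 to 0.971 and 1.12e-15 to 0.802, and none passed with an estimated correlation (adjusted p = 0.790, 0.847 and 0.790 with an estimated correlation). In the polyamine, antioxidant, apoptosis and chaperone lists the median, the mean and camera's direction differed in sign.

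The test was edgeR's as above, and groups did not overlap in 2445 genes, where chance gives 5.71% of genes. The count of 598 was 99 without aged replicate 2, 111 without spermidine replicate 2, 167 without aged replicate 3 or without spermidine replicate 3, 273 without young replicate 1, 281 without young replicate 3 and 1127 without spermidine replicate 4. It was 124 with only the aged and spermidine libraries in the fit, 259 with total count scaling and 1366 with DESeq2. Of 30 list members named by rule that passed, Vamp8 and Ern1 alone kept their call whichever library was left out, and 28 lost it without spermidine replicate 2, 27 without aged replicate 2, 26 without aged replicate 3 and 25 without spermidine replicate 3.

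Most of the genes that differed between aged and young oocytes had the opposite sign with spermidine, 1974 of 2189 (90.2%). A total of 372 passed in both comparisons in opposite directions, 185 of them higher in aged oocytes and lower with spermidine and 187 the other way, and 16 passed in the same direction. Anxa5 was at 122 CPM ± 7.72 (SD, n = 3) in young oocytes, so that its fall in aged oocytes and its rise with spermidine were of similar size (-1.80 and 1.72). Stk36 (3.01 and -2.39), Ttll10 (3.31 and -2.26) and Pcp4l1 (3.48 and -4.33) rose in aged oocytes and fell with spermidine, and Snapin (-1.47 and 1.97) did the reverse. Pcp4l1 was low in the young libraries, at 0.553, 1.26 and 0.178 CPM, and its rise ran from 3 to 4.39 with 1 library left out. Plpp1 went from 130 CPM ± 12.9 (SD, n = 3) in young to 39.1 CPM ± 0.842 (SD, n = 3) in aged and 86.8 CPM ± 8.84 (SD, n = 4) in spermidine oocytes. Rilpl1, Zfp961 and Zfp979 also rose and fell, as did Mark2, at 19.0 CPM ± 2.50 (SD, n = 3), 42.4 CPM ± 0.635 (SD, n = 3) and 18.1 CPM ± 2.72 (SD, n = 4).

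Both comparisons use the same aged libraries, and that alone gives opposite signs. With no group effect, 100 simulated draws gave a median correlation of fold changes across genes, which are not independent replicates, of -0.532, against -0.472 observed, and a covariance of -0.0567 against -0.207 observed, a difference of -0.150. In those draws the most changed genes had opposite signs in 85.7% of cases, and in 50 draws where only the young group differed, 68.9% of the genes that passed did. The number passing both ways was at most 1 in either simulation. Neither held a true difference between aged and spermidine, so such a low number followed from their construction and is no measure for the 372. Independent lists would share 29.1 and 24.03 genes in the 2 opposite directions. Part of the excess over those values may come from the shared aged libraries. The simulated genes varied independently, so trends shared by the genes of a library are not in those values. Another grouping, aged replicate 1 with spermidine replicates 1 and 2 against the other aged and spermidine libraries, gave 536 opposite changes. Of the 372 genes, 354 did not pass in spermidine minus young, which does not show that they were equal to young. The count of 372 was 63 without aged replicate 2, 76 without spermidine replicate 2, 110 without spermidine replicate 3, and 112 without aged replicate 3. It was 139, 241 and 152 without young replicates 1, 2 and 3, 663 without spermidine replicate 4, 149 with total count scaling and 834 with DESeq2.

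**Figure D3:**
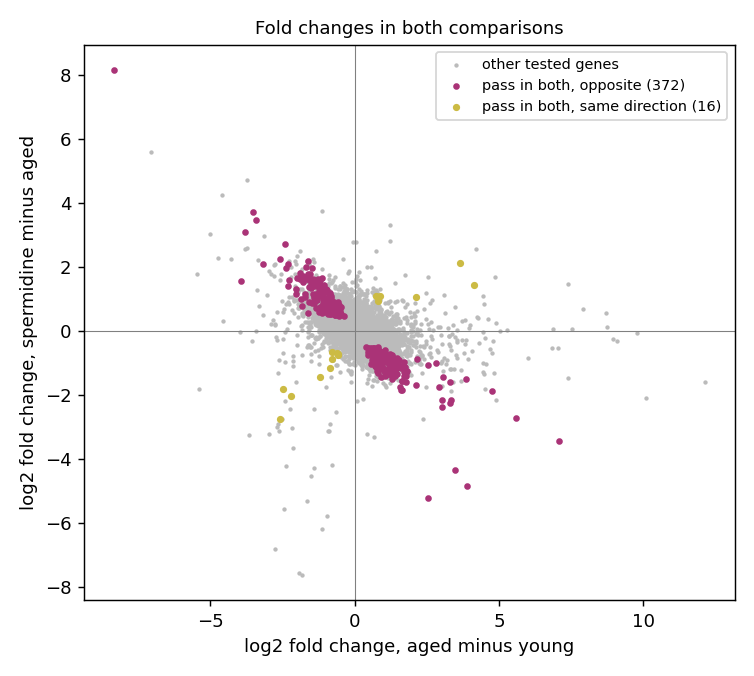
Log2 fold change of spermidine minus aged (vertical axis) against that of aged minus young (horizontal axis), one point per tested gene. The 372 genes that passed in both comparisons with opposite signs and the 16 with the same sign are coloured; the axes share the aged libraries, which alone gives a negative slope.

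**Figure D4:**
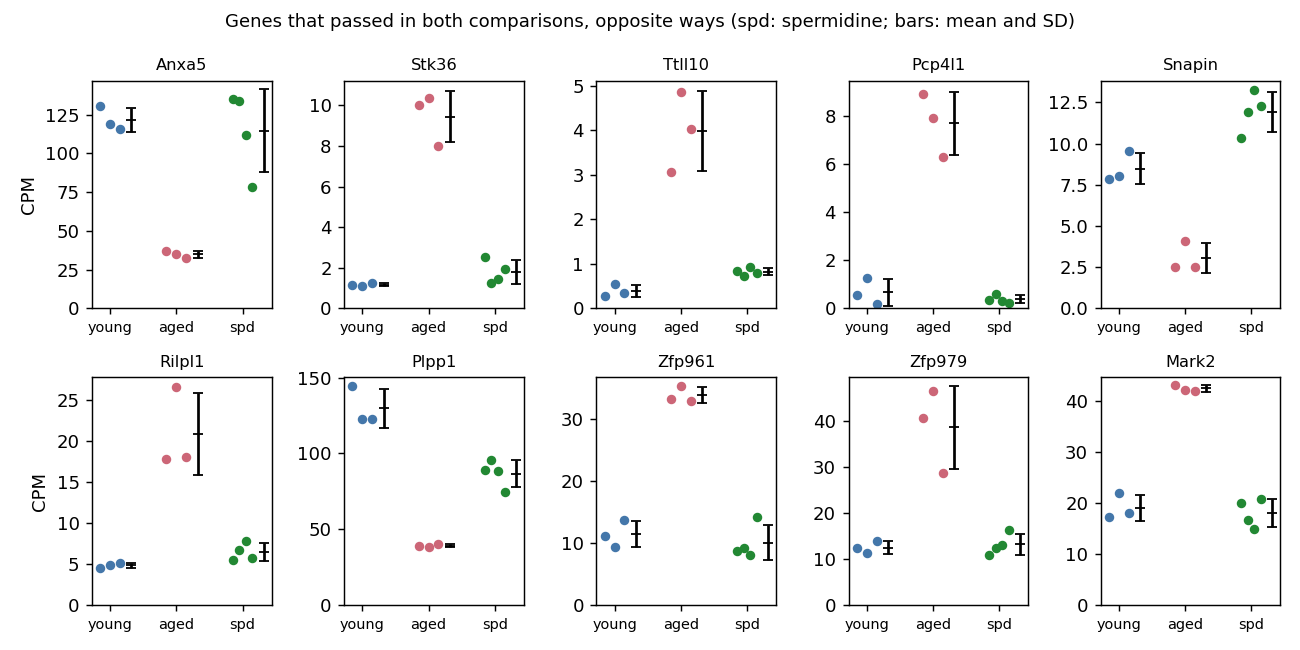
CPM of the 10 genes named by the rule for opposite changes, one point per library, with the group mean and SD beside the points and each vertical axis starting at 0. Plpp1 is at 130 CPM in young, 39.1 CPM in aged and 86.8 CPM in spermidine oocytes.

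Between spermidine and young oocytes, 424 genes were higher and 236 lower with spermidine, and 422 of these 660 changed by at least 2-fold. Manba was at 66.8 CPM ± 12.5 (SD, n = 4) with spermidine, against 0.339 CPM in young oocytes, and Agtpbp1 at 21.8 CPM ± 3.03 (SD, n = 4), against 166 CPM. Tceal8 rose from 56.8 CPM ± 4.98 (SD, n = 3) in young oocytes to 506 CPM ± 35.9 (SD, n = 4), and was at 245 CPM ± 35.3 (SD, n = 3) in aged oocytes. Of the 2189 genes changed in aged minus young, 454 passed here in the same direction, 290 higher and 164 lower, and 0 in the opposite one. Both comparisons use the same young libraries, which alone gives like signs. In the 100 draws with no group effect the correlation of fold changes across genes was 0.541, against 0.742 observed, the covariance 0.0583 against 0.428, a difference of 0.369, and the most changed genes had the same sign in 86.0% of cases, against 92.7% of the 2189. At most 1 gene passed both in those draws. They held no true difference, so hardly any gene could pass whatever the young libraries share, and that number is no measure for the 454. Independent lists would share 41.2 higher and 19.03 lower genes. Part of the excess may come from the shared young libraries, and the draws held no trends shared by the genes of a library.

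Higher than in young oocytes were also Srgn (4.18, SE 0.56), the lectin gene Clec12a (1.90, SE 0.25), Cldn34b2 (1.83, SE 0.19), Tsc22d1 (1.77, SE 0.25), the cytokine gene Il17f (1.75, SE 0.24), Ccdc105 (1.69, SE 0.17), Cnep1r1 (1.61, SE 0.19) and B3gnt2 (1.61, SE 0.18). Lower were Sirpb1c (-3.87, SE 0.29), the xanthine dehydrogenase gene Xdh (-3.79, SE 0.41), Lzts1 (-3.20, SE 0.28), Bcat2 (-2.70, SE 0.51), Slc23a3 (-2.57, SE 0.28), Slc12a8 (-2.43, SE 0.38) and Utp23 (-1.62, SE 0.22). So were the histocompatibility genes H2-T22 (-2.63, SE 0.38) and H2-T10 (-1.67, SE 0.22), whose reads can be shared between paralogs. The 20 calls named by fold change were kept whichever 1 library was left out. In those fits the value of Srgn ran from 3.75 to 5.26 and that of Xdh from -4.41 to -3.58. Those of Bcat2 and Slc12a8 were lost without aged replicate 1 and spermidine replicate 1 together, and that of Bcat2 also without a filter and with only the 2 groups in the fit.

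Of 87 oxidative phosphorylation genes 0 passed by edgeR and 1 by DESeq2, with 13 at an unadjusted p under 0.05, and of 75 cytosolic ribosomal genes 0 and 2, with 10. Mrpl39 (0.64, SE 0.14) of 78 mitochondrial ribosome genes was higher and Psma1 (-0.57, SE 0.14) of 31 proteasome genes lower, and adjusted over the list alone 0 genes of these 4 lists passed. Camera called the 4 lists lower (adjusted p = 0.0175, 0.0123, 0.0299 and 0.00407, and adjusted p = 0.913 with an estimated correlation for each). Over the alternatives its adjusted p began at 5.04e-05, 2.46e-08, 0.00312 and 0.00027 and ended at 0.913. The medians were -0.13, -0.14, -0.12 and -0.19, and with total count scaling the first 3 turned positive, to 0.05, 0.05 and 0.07, their calls being lost, while that of the proteasome list was -0.03. Among matched random lists the 4 medians lay at percentiles 16.18, 20.18, 8.33 and 11.2, within the spread of the random lists, which centred on -0.11, -0.11, -0.07 and -0.14. These 3 calls were lost without young replicate 1, without spermidine replicate 4, under a stricter filter and after length and GC correction. In the low GC class the mitochondrial ribosome call was lost, and with fry all 4, while the high class holds 1 young and 1 spermidine library and does not compare the groups. The blood and immune list was also called lower (camera adjusted p = 0.0175, from 2.63e-22 over its alternatives to an adjusted p = 0.913 with an estimated correlation). Of its 9 genes 0 passed by edgeR and 1 by DESeq2, with 6 at an unadjusted p under 0.05 and 6 lower adjusted over the list alone. Its median with undetected genes at their bounds was -4.82, the bound of Cd74, which stood at 1.47, 0 and 0.801 CPM in the young libraries. Of the 9 log2 fold changes 8 were negative and 1 positive. The most abundant members, C1qb and H2-Aa, overlapped between the groups. C1qb stood at 14.5 to 20.5 CPM in young and 8.72 to 17.1 CPM in spermidine libraries, and H2-Aa at 20.4 to 42.4 and 22.9 to 79.1 CPM. Both were named after their values were seen. Haemoglobin summed to 19.9 and 13.5 CPM in young replicates 1 and 3, and the list's call was lost without young replicate 1, without spermidine replicate 1 or 4, with fry and after length and GC correction.

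In other lists, none of which passed camera in the fit described above, Optn (1.05, SE 0.19) rose and Nipsnap1 (-0.63, SE 0.15) fell among mitophagy genes (camera adjusted p = 0.597, with 1 higher and 2 lower adjusted over the list alone). Glb1 (1.23, SE 0.19), Hexa (0.98, SE 0.24) and Scarb2 (1.24, SE 0.31) rose among lysosome genes (4 higher and 1 lower adjusted over the list alone). Tfam (0.72, SE 0.17), the mitochondrial transcription factor gene, and Acadl (1.03, SE 0.22) and Echs1 (0.67, SE 0.15) of fatty acid oxidation were higher. So were Pdha1 (0.74, SE 0.14), Stx17 (0.84, SE 0.17), Parp1 (0.78, SE 0.17), Ndc80 (0.92, SE 0.13), Aurkc (1.28, SE 0.30), Edem1 (1.76, SE 0.26), Nr5a2 (0.78, SE 0.19) and, of sperm binding, Rab27a (0.61, SE 0.14) and Nsf (0.66, SE 0.17). Fetub (-0.92, SE 0.14) and Tet1 (-0.80, SE 0.20) were lower. Adjusted over the list alone 2 genes of mitochondrial dynamics, 2 of fatty acid oxidation, 2 of spindle and 2 of sperm binding were higher. In the mitophagy, apoptosis, oocyte-specific, maternal mRNA and chaperone lists the median, the mean and camera's direction differed in sign. Of 18 polyamine metabolism genes 0 passed by edgeR and 0 by DESeq2, with 4 at an unadjusted p under 0.05.

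By edgeR's test the count of 660 was 283 without young replicate 1, 326 without young replicate 3, 376 without spermidine replicate 2, 273 under a stricter filter and 1099 with DESeq2, and groups did not overlap in 2589 genes, where chance gives 5.71%. With total count scaling the split was 605 higher and 126 lower and the median log2 fold change of all genes moved from 0.04 to 0.23, and with DESeq2 the split was 579 and 520. Of 21 list members named by rule that passed, 4 kept their call whichever library was left out, Glb1, Fetub, Ndc80 and Edem1, and 17 lost it without young replicate 1.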

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

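The spermidine group has 4 libraries, and for 55 measures (8 of the libraries and 47 named genes) the gap between its most distant library and the next, divided by the range, was set against Dixon's 95% critical value. Chance gives about 5% of such groups a library beyond it, and 4 measures had one. Bcat2 (ratio 0.875) stood at 20.3 CPM in spermidine replicate 4 against 3.36 to 5.48 CPM in the others. Prex2 (ratio 0.899) was at 46.0 CPM in spermidine replicate 4 against 20.7 to 23.3 CPM. Galnt6 (ratio 0.894) was at 122 CPM in spermidine replicate 3 against 52.3 to 59.7 CPM. Ern1 (ratio 0.841) was at 15.7 CPM in spermidine replicate 2 against 20.98 to 21.98 CPM. No explanation of these values was tested.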

How the results depend on the processing

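Length and GC correction, total count scaling, the joint removal of aged replicate 1 and spermidine replicate 1, and the GC classes were chosen after seeing the data. Genes that passed here and under another setting had the same sign in both, and the lists called here kept the direction of camera's test; medians of 3 lists in spermidine minus young changed sign with total count scaling. Where a setting's construction does not show it, the cause was not tested. Over the fits that leave out 1 library, changed genes ranged from 827 to 2362 (aged minus young), 99 to 1127 (spermidine minus aged) and 283 to 874 (spermidine minus young), opposite changes from 63 to 663, and lists passing from 4 to 5, 5 to 10 and 1 to 5. Of the largest named changes, 27 of 29, 19 of 24 and 20 of 20 kept their call in every such fit; of named list members that passed, 30 of 72, 2 of 30 and 4 of 21 did. Depth limits the genes tested, and 3 counts over a group set the floor. The test per transcript was not run, since the table is per gene. DESeq2 gave no adjusted p for 2 genes in each comparison. Of 567 list results per comparison under other settings, 6, 27 and 36 lost a call, 16, 17 and 2 gained one and 0, 0 and 1 reversed.

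The stricter filter, which tests fewer genes, gave 1179 (aged minus young), 273 (spermidine minus young) and 1 list for spermidine minus young. The threshold of 2-fold gave 940, 225 and 422 genes and 174 opposite changes. Fitting only the 2 groups gave 124 for spermidine minus aged. DESeq2 gave 1366 and 1099 for the spermidine comparisons and 834 opposite changes. Total count scaling gave 259 (spermidine minus aged), 149 opposite changes and 2 lists for spermidine minus young, and length and GC correction left 1 such list. With an estimated correlation 0 lists passed in each comparison, and fry passed 0 for spermidine minus young. Without aged replicate 1 and spermidine replicate 1 the counts were 2570, 656 and 794, with 434 opposite changes.

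Equal replicate numbers share no known origin, correlations of same-numbered deviations ran from -0.275 to 0.408, and 3 of 9 libraries correlated best with their own number, so the numbers were not taken as pairs. A replicate block gave 998 genes for spermidine minus aged, 572 opposite changes and 2 lists for spermidine minus young. There the calls of the oxidative phosphorylation, mitochondrial ribosome and cytosolic ribosomal lists were lost. Number 4 occurs in the spermidine group alone, so the block fits spermidine replicate 4 exactly and takes it out of the comparisons. Leaving that library out gave 1127 genes and 663 opposite changes, with the same calls lost, so these shifts cannot be credited to blocking. With the block the lysosome list passed as lower in spermidine minus aged (adjusted p = 0.0376, from 0.0376 to 0.844 over its alternatives, and adjusted p = 0.790 with an estimated correlation), and the block changed no other list call.

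The GC class of a library is the sign of its GC trend. It was made from the expression values themselves after the other splits of the samples were seen, and is not a labelled batch. It leaves aged replicate 1 alone in the low class and young replicate 2 and spermidine replicate 4 alone in the high class, each assumed to vary like the other groups. The class as a term gave 986 and 1067 genes for the spermidine comparisons and 651 opposite changes, and since it comes from the same values, the larger counts add no evidence. The low class alone passed 7 lists for aged minus young and the high class 2 for spermidine minus aged. In the high class the oocyte-specific list, not called over all libraries, passed as higher in spermidine minus young, with a median of 0.54 against 0.10 and camera's direction reversed. The lysosome and sperm binding lists also passed as higher there, with medians of 0.20 and 0.47 (adjusted p = 0.0115 for both, the lowest over their alternatives), and none of the 3 with an estimated correlation (adjusted p = 0.913 with an estimated correlation over all libraries). That class sets spermidine replicate 4 against young replicate 2, with a spread taken from aged replicates 2 and 3, so it compares those 2 libraries and not the groups.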

Other observations

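The pathway sets, the length and GC correction, the GC classes and the test of library depth were chosen only after the data were seen. The pathway names in the authors' deposited table make 321 sets, of which camera called 13 higher and 7 lower in spermidine minus aged, 1 higher and 9 lower in aged minus young, and 1 higher and 3 lower in spermidine minus young, and 0 with an estimated correlation (adjusted p = 0.679, 0.754 and 0.998 for the lowest). The first by p of the higher sets in spermidine minus aged was ribosome, with 135 genes and a median log2 fold change of 0.24 (camera adjusted p = 3.96e-06, and adjusted p = 0.679 with an estimated correlation), and the highest median was that of xenobiotic metabolism by cytochrome P450 (0.47 over 31 genes, 2 of them higher, camera adjusted p = 0.000167, and adjusted p = 0.679 with an estimated correlation). The mitophagy and Wnt sets that follow were picked after the data were seen. The set named mitophagy had 56 tested genes, of which 1 was higher and 5 lower in spermidine minus aged, with a median log2 fold change of -0.29 (camera adjusted p = 0.0195 over 321 pathways, and adjusted p = 0.679 with an estimated correlation). In aged minus young its median was 0.36, with 10 genes higher and 3 lower (camera adjusted p = 0.204). The Wnt signaling set was lower in spermidine minus aged, with 10 of 95 genes lower and 2 higher (median -0.28, camera adjusted p = 0.0294, and adjusted p = 0.679 with an estimated correlation). The authors' deposited table has 2105 genes with a q-value under 0.05 for aged against young and 737 for spermidine against aged, of which 1830 and 562 also passed here, all with the same sign.

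The lower oxidative phosphorylation and mitochondrial ribosome lists in aged oocytes and their higher levels with spermidine were set against length and GC trends and against aged replicate 1. After length and GC correction the lists still passed camera with its preset correlation (larger adjusted p = 0.000228 for aged minus young, 0.0109 for the cytosolic ribosomal list and 0.0152 for spermidine minus aged). None passed with an estimated correlation (adjusted p = 0.855 for aged minus young, and 0.889 and 0.508 for the 2 lists in spermidine minus aged). The oxidative phosphorylation medians shrank from -0.40 to -0.23 and from 0.32 to 0.14, so the correction removed a part of the shifts and not the whole. The preset test passed as many lists in other splits of the samples, as given below, so passing it does not decide on the trends as a cause. Without aged replicate 1 the larger camera adjusted p values were 5.26e-07 and 0.000512, a test with the same limit. The oxidative phosphorylation medians were then -0.45 and 0.33, so the shifts did not rest on that library alone. Splits of the samples passed as many lists in 19 of 35 cases, the real one included, for spermidine minus aged (7 lists, highest other 10) and 17 of 35, the real one included, for spermidine minus young (5, highest other 13), so chance could not be excluded there. For aged minus young all 10 splits passed at least the 4 lists of the real one (highest other 6). The number of lists called therefore did not set the real grouping apart, and 10 splits are too few for a share under 0.05 in any case. With this, part of the shifts may be technical, and effects of age and spermidine on these genes stay open and untested.

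The opposite run of changes was set against noise in the shared aged libraries and against length and GC trends. With separate aged libraries on each side the covariance was negative in all 6 assignments (highest -0.0920), which argues against noise independent between aged libraries as the whole cause. Aged replicates 2 and 3 were alike, and the assignments that kept them on the same side gave the weakest covariances (-0.0920 and -0.0982). After length and GC correction the covariance was -0.163, below the lowest of the simulations without group effects (-0.0685). Those simulations drew each gene independently, so this argues only against these trends with such noise as the whole cause. Other structure shared by the genes of a library stays open. Yet 2 of 35 splits of the aged and spermidine libraries, the real one included, gave at least 372 opposite changes (highest other 536) and 3 of 35 at least 598 changed genes (highest other 1079, for aged replicate 1 with spermidine replicates 1 and 2), so chance could not be excluded for either count and a structure of the samples other than their group is a candidate source. A further split, aged replicates 2 and 3 with spermidine replicate 4 against the rest, gave 684 genes and parts the libraries exactly by their GC class, and since the low class has 1 aged library and the high class 1 spermidine library, counts within a class cannot weigh one against the other. An effect of spermidine stays open beside that structure.

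A total of 280 genes lay at least 2-fold from young in both other groups in the same direction, 204 higher and 76 lower. Library totals differed by at most 1.19-fold, which decides nothing about depth, since the genes were chosen for lying at least 2-fold apart. Of 272 such genes placed on chromosomes, 30 had a neighbour in the set, against 11.2 on average and 19 at the 95th percentile of 10000 random sets, a factor of 2.68, where genes 2-fold apart between spermidine and aged had 12 and a factor of 1.58. A difference in genetic background between the young animals and the others may be part of this, as a hypothesis; neighbouring genes that change together with age would look alike, and the design does not separate age from origin. For spermidine minus young 1 of 35 splits, the real one, gave 660 genes and the highest other 61. That share is under 0.05 and argues against chance, but it is the smallest that 35 splits allow. It was not adjusted over the splits of other results, and it does not separate age or spermidine from origin. For aged minus young (2189 genes, highest other 13) the 10 splits are too few for a share under 0.05.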
